A study of Mus musculus with 9 samples.

How the data were processed

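Expression of genes was measured by RNA-seq in 9 libraries of mouse B cells: B2 cells from spleen, and B1 and B2B1 cells from the peritoneal cavity, with 3 libraries each. Per the labels' protocols, RNA was isolated with a Qiagen RNeasy micro kit and libraries were made with the Illumina TruSeq RNA kit. Per the submitters' processing notes, CASAVA 1.8.2 and kallisto were used with the genome build mm10. The version of kallisto, the transcript set and the way transcripts were summed to genes are not given in the sources used here. The deposited gene table holds TPM for 22178 gene symbols, none of them duplicated. TPM divide each gene's estimated reads by its effective length and by the library total, so a gene's value depends on all others in the library, and depth cannot be read from them. The listed genes of a library sum to 894515 to 943043 TPM. A second deposited table gives the TPM of a signature of 28 genes. For 26 of these its values equal those of the gene table, and the other 2 were not used. How the submitters chose the signature is not stated.

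Libraries were assigned to groups by their labels. No pair of libraries was identical (0 of 36 pairs). Symbols were matched to RefSeq (20938) and to GENCODE M21 on GRCm38 (21142), from which the coordinates were taken.

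Values were analysed as log2(TPM + 1) for the 11099 genes with a mean TPM of at least 1 over the 9 libraries. Fold changes on this scale understate the change of low genes. The 3 comparisons were fitted in R 4.3.3 with limma 3.58.1 (lmFit, contrasts.fit and eBayes with trend) in one model over all 9 libraries, so that they share one estimate of the spread, with no covariate. The prior degrees of freedom were 2.92. P-values are two-sided and adjusted by the Benjamini-Hochberg method within a comparison, and a gene was called at an adjusted p under 0.05. With 3 libraries against 3, an exact permutation test cannot go below 0.1, so single values were not tested that way. Gene lists were tested with camera in limma, with a preset correlation between genes of 0.01, adjusted over the 23 lists with at least 3 tested members, and again with an estimated correlation. A count "adjusted over the list alone" applies the adjustment to the list's members only. Because these are TPM and not counts, no count model was used, and no interval for counting error could be given. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

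Before the data were examined, the groups, the tests, the gene lists, the rule for named genes and the first set of alternatives were fixed. The rule took, per comparison, the 10 called genes with the highest and the 10 with the lowest log2 fold change among those with a mean TPM of at least 5 and groups that did not overlap, leaving out gene models named only by number, then up to 4 members of each list with the smallest adjusted p, and any member needed to show that it did not pass. Some genes that the rule names are not reported here. Single members that make up a small count (Klf2, Cd86 and Siglecg), Xist, Ddx3y, Rpl26, Gm15772 and the genes of the closing observations were chosen after their values were seen. The lists covered B-1 cell, follicular and marginal zone markers, plasma cell and secretory genes, germinal centre genes, BCR signalling components, inhibitory receptors and phosphatases, immediate early genes, regulatory B cell genes, homing and adhesion receptors, cell cycle genes, B cell transcription factors, survival and apoptosis genes, interferon-stimulated genes, antigen presentation and costimulation genes, innate sensors, glycolysis, lipid uptake and metabolism, and markers of macrophages, T cells, NK cells, neutrophils, mast cells and eosinophils, dendritic cells, erythroid cells, and mesothelium and stroma. Some genes stand in more than one list, such as Cd5, Zbtb32, Icosl and Notch2. Lists of immunoglobulin constant genes (apart from Igj), BCR variable segments and mitochondrially encoded mRNAs were not analysed here, and neither was the planned comparison of the immunoglobulin share.

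The position of B2B1 was computed per gene as the difference of B2B1 from B2 divided by that of B1 from B2, on mean log2 values. Because both comparisons with B2 share their control libraries, 100 simulations with no effect gave the correlation and covariance that chance produces. The test of differences was checked on simulated data with 200 changed genes per comparison among 11099. For B1 against B2 it recovered 55.2%, 89.6% and 98.5% of genes changed 1.5-fold, 2-fold and 4-fold, and 4.14% of its calls were false. For B2B1 against B2 the shares were 68.7%, 92.5% and 97.0%, with 7.03% false, and for B2B1 against B1 55.2%, 83.6% and 95.5%, with 3.7% false. The simulated noise was drawn independently for each gene from the fitted spread, in a single run per comparison. In the real data genes are correlated and far more were called, so these shares need not hold there.

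The alternatives covered other pseudocounts (0.1, 0.5 and 5), other filters, median-of-ratios scaling and quantile normalization of the TPM, robust and library-weighted fits, fits of only the 6 libraries compared, a fold threshold, the replicate number as a block, and leaving out each library in turn. Those chosen after the data were seen were both scalings for the gene lists, a covariate for Xist above 10 TPM, and leaving out B2B1 library 1 together with B1 library 2.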

Results

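RNA was sequenced from 3 groups of mouse B cells, with 3 libraries per group. The B2 cells, conventional B cells, came from the spleen of mice with the strain label VH12B1-8/Vk4. The B1 cells, the B cell class typical of body cavities, came from the peritoneal cavity of mice with the strain label B1-8VH12/Vk4. The B2B1 cells also came from the peritoneal cavity under that strain label, and a switch of their B cell receptor (BCR) had been induced about 30 days before they were isolated. The values were TPM, each gene's length-corrected share of the transcripts of a library, for 22178 genes. TPM keep no read counts, so the sequencing depth of each library is unknown. The listed genes summed to between 894515 and 943043 TPM per library. In each library 10711 to 10945 genes reached 1 TPM. Immunoglobulin chain genes, the variable segments of the BCR and mitochondrially encoded genes were not analysed here. Nothing in the labels says that the 3 libraries of a group came from separate mice, so p-values measure only the spread between these samples.

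The libraries separated by group. The first principal component of the 11099 tested genes carried 70.3% of the variance and set the B2 libraries (scores −66.9 to −65.6) apart from the peritoneal libraries (23.9 to 44.2). The second carried 13.3% and parted the B2B1 libraries (17.7 to 29.3) from the B1 libraries (−30 to −19.6). B1 library 2 stood apart on the third component, which carried 4.12% of the variance, at −29.4 against 10.8 and 11.5 for B1 libraries 1 and 3. Across genes, which are not independent replicates, Pearson's r between libraries was 0.853 to 0.88 for B2 against B2B1, 0.879 to 0.897 for B2 against B1, and 0.95 to 0.966 for B2B1 against B1. Within groups it was 0.976 to 0.989. Xist, the transcript of the inactive X chromosome, reached 180.4 to 298.1 TPM in B2 libraries 1 and 3, B2B1 library 3 and all B1 libraries, and stayed at 0.355 to 0.461 TPM in B2 library 2 and B2B1 libraries 1 and 2. In those 3 libraries the Y-linked Ddx3y stood at 56.9 to 75.3 TPM.

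The comparison of B1 with B2 cells addressed which transcripts set peritoneal B1 cells apart from splenic B2 cells. S100a6, a calcium-binding protein, averaged 9.07 ± 2.80 TPM in B2 and 3317 ± 504 TPM in B1 (mean ± SD, n = 3 here and below), a log2 fold change of 8.39 ± 0.20 (SE, limma adjusted p = 8.99e-09). Its neighbour S100a4 was at 0.906 ± 0.292 TPM in B2 and 973 ± 305 TPM in B1. Zbtb32, a transcriptional repressor, was higher in B1 by 7.53 ± 0.115 on the log2 scale (1.28 ± 0.347 against 420 ± 48.1 TPM; adjusted p = 1.17e-09). Fcer2a, the low-affinity IgE receptor of follicular B cells, was at 1187 ± 87.7 TPM in B2 and 9.24 ± 2.85 TPM in B1 (log2 fold change −6.90 ± 0.20, adjusted p = 2.87e-08). Cr2, the complement receptor that binds C3 fragments, was at 621 ± 45.6 TPM in B2 and 6.88 ± 2.44 TPM in B1 (log2 fold change −6.34 ± 0.25, adjusted p = 1.94e-07).

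In the mouse genome build GRCm38 (GENCODE M21), S100a4 lies on chromosome 3 from 90603771 to 90606045 and S100a6 on the same chromosome from 90612882 to 90624181. Zbtb32 lies on chromosome 7 from 30589681 to 30598909, and Fcer2a on chromosome 8 from 3681737 to 3694175. The other genes with the highest fold changes in B1 were Gnb3, Gas7, Tnfrsf8, Fgl2, Anxa2, AI607873 and Tppp, with log2 fold changes from 6.03 to 7.004. Icosl, Il9r, Ccr6, Vpreb3, Lrrk2, Fam101b, Emid1 and Treml2 joined Fcer2a and Cr2 at the low end, with log2 fold changes from −6.65 to −5.42. Il9r, the receptor chain for interleukin 9, was at 379 ± 16.8 TPM in B2 and 3.63 ± 1.53 TPM in B1. In each of these 20 genes the 3 B1 values and the 3 B2 values did not overlap, as the choice of these genes required.

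Markers of B-1 cells were higher in B1: 15 of the 17 tested were higher and 0 were lower (15 and 0 adjusted over the list alone), with a median log2 fold change 3.61 above that of all genes (camera adjusted p = 1.33e-14, adjusted p = 0.00584 with an estimated correlation). Lgals1, which encodes galectin 1, was at 12.8 ± 1.32 TPM in B2 and 537 ± 57.1 TPM in B1, and the tetraspanin Cd9 at 15.5 ± 0.507 and 145 ± 8.57 TPM. Cd5, a surface receptor that dampens BCR signals, was at 0.874 ± 0.243 and 18.8 ± 4.88 TPM (log2 fold change 3.38 ± 0.20, adjusted p = 2.21e-06). Ctla4 was listed at 0 in all 3 B2 libraries and averaged 68.3 ± 43.3 TPM in B1. Pdcd1lg2 and Siglecg did not pass, although Siglecg was called higher with median-of-ratios scaling (log2 fold change 0.23). Of the genes that the submitters deposited as a signature, 13 of 13 tested with a higher B1 mean and 12 of 12 with a lower one were called that way, with the same counts adjusted over each list alone (camera adjusted p = 1.33e-14 and 2.44e-09; adjusted p = 0.00337 and 0.0173 with an estimated correlation). The submitters chose that signature, possibly on these samples. Its parts were split here by the B1 and B2 means of these same libraries. Direction in this comparison was thus fixed in advance, so the counts and camera p-values are not independent evidence of it. Pstpip2, an adaptor of the cytoskeleton, is one of its members, at 0.829 ± 0.186 TPM in B2 and 117 ± 11.4 TPM in B1.

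Follicular markers were lower in B1, with 8 of 11 lower and 1 higher (the same counts adjusted over the list alone, median −2.34 relative to all genes, camera adjusted p = 0.00156, adjusted p = 0.343 with an estimated correlation). Cd55, a complement regulator, was at 519 ± 46.7 TPM in B2 and 139 ± 17.0 TPM in B1, and Klf2, a transcription factor of lymphocyte trafficking, was the member that was higher. The call of Klf2 was lost without B2 library 1 or 3 (log2 fold changes 0.46 and 0.42) or B1 library 2 or 3 (0.36 and 0.41). All 10 marginal zone markers were lower (10 adjusted over the list alone, median −1.02 relative to all genes, camera adjusted p = 9.71e-05, adjusted p = 0.124 with an estimated correlation). Among them Asb2 fell to 0.055 ± 0.0199 TPM in B1 from 18.2 ± 2.61 in B2, and Notch2, a receptor needed for marginal zone B cells, stood at 86.0 ± 5.93 against 178 ± 10.4 TPM. Antigen presentation and costimulation genes were lower for 12 of 14 members and higher for 1 (the same adjusted over the list alone, median −0.85 relative to all genes, camera adjusted p = 0.00162, adjusted p = 0.391 with an estimated correlation). H2-Ob, a gene of the class II pathway, was at 1150 ± 40.9 TPM in B2 and 386 ± 49.8 TPM in B1 (log2 fold change −1.58 ± 0.10, adjusted p = 2.37e-06). Cd80, a costimulatory ligand of T cells, went the other way, from 0.868 ± 0.106 TPM in B2 to 55.7 ± 13.4 TPM in B1.

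Plasma cell and secretory genes were higher in B1 for 7 of 14 members and lower for 0 (the same adjusted over the list alone, camera adjusted p = 0.0033, adjusted p = 0.343 with an estimated correlation). Prdm1, the regulator of plasma cell differentiation, was at 0.586 ± 0.157 TPM in B2 and 16.0 ± 7.003 TPM in B1, and Derl3, of endoplasmic reticulum protein disposal, at 3.22 ± 0.964 and 36.7 ± 15.6 TPM. Glycolysis genes were higher for 9 of 16 and lower for 3 (the same adjusted over the list alone, camera adjusted p = 0.00762, adjusted p = 0.412 with an estimated correlation), with Tpi1 at 64.8 ± 3.64 TPM in B2 and 157 ± 11.6 TPM in B1. Innate sensors were higher for 7 of 14 and lower for 3 (the same adjusted over the list alone, camera adjusted p = 0.0208, adjusted p = 0.391 with an estimated correlation). Nod2, a sensor of bacterial peptidoglycan fragments, was at 2.11 ± 0.434 TPM in B2 and 21.2 ± 3.00 TPM in B1. Regulatory B cell genes were higher for 6 of 12 and lower for 3 (7 and 3 adjusted over the list alone, camera adjusted p = 0.02, adjusted p = 0.215 with an estimated correlation). Their lower members included Il12a, at 51.3 ± 4.75 TPM in B2 and 2.13 ± 1.48 TPM in B1, which encodes a subunit of interleukin 12. With the TPM rescaled by median-of-ratios factors, the list calls of innate sensors and regulatory B cell genes were lost (camera adjusted p = 0.065 and 0.101), and quantile normalization also ended the call of the regulatory genes (0.0779).

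Another set of lists was not called in B1 against B2. Homing and adhesion receptors were split between 5 higher and 6 lower of 17 (camera adjusted p = 0.471). Itgb1, the integrin beta 1 chain, was at 24.6 ± 1.66 TPM in B2 and 424 ± 21.5 TPM in B1, and the chemokine receptor Ccr6 at 232 ± 30.3 and 2.07 ± 1.15 TPM. BCR signalling components had 1 member higher and 7 lower of 18 (camera adjusted p = 0.414), with Rasgrp3, an activator of Ras, at 156 ± 15.8 TPM in B2 and 5.31 ± 1.60 TPM in B1. Inhibitory receptors and phosphatases had 4 higher and 8 lower of 15 (5 and 8 adjusted over the list alone, camera adjusted p = 0.896), immediate early genes 3 higher and 8 lower of 18 (0.896), and B cell transcription factors 6 higher and 12 lower of 23 (0.471). Survival and apoptosis genes had 7 higher and 5 lower of 15 (camera adjusted p = 0.218), germinal centre genes 2 and 2 of 6 (0.697), lipid uptake and metabolism genes 2 and 12 of 20 (0.18), dendritic cell markers 1 and 2 of 5 (0.807) and T cell markers 1 and 1 of 4 (0.428). Where not stated otherwise, these counts were the same adjusted over the list alone. The camera direction was up for inhibitory receptors and for homing receptors although their median log2 fold changes were −0.19 and −0.17 (−0.054 and −0.039 relative to all genes) and the mean of the latter was −0.07.

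Some groups moved with single libraries. Interferon-stimulated genes had 1 member higher and 9 lower of 18 in B1 against B2 (the same adjusted over the list alone, camera adjusted p = 0.117), with Irf7 at 66.1 ± 8.60 TPM in B2 and 6.74 ± 0.0602 TPM in B1. Their list was called lower without B2B1 library 1 (camera adjusted p = 0.000797), without B2B1 library 2 (0.0487), with B2B1 library 1 and B1 library 2 both left out (0.00203), with median-of-ratios scaling (0.0239) and with quantile normalization (0.0404). Cell cycle genes had 1 higher and 1 lower of 21 (0 and 0 adjusted over the list alone, 4 at an unadjusted p under 0.05 by limma, camera adjusted p = 0.118), and became a called list without B1 library 1 or 3 (camera adjusted p = 0.0216 and 0.04). Their mean log2 value was 4.13 in B1 library 2 against 2.85 and 2.89 in B1 libraries 1 and 3. Macrophage markers had 1 of 7 higher, the F4/80 gene Emr1 (0.384 ± 0.0974 TPM in B2, 18.1 ± 3.90 in B1), and 0 lower (the same adjusted over the list alone, camera adjusted p = 0.0222, adjusted p = 0.522 with an estimated correlation). That list call was lost without B1 library 3 (camera adjusted p = 0.0594), with median-of-ratios scaling (0.101) and with quantile normalization (0.124). Lyz2, at 0.965 ± 0.546 TPM in B2 and 17.9 ± 15.2 TPM in B1, did not pass, and was called without B1 library 1 (log2 fold change 3.81) or B2B1 library 1 (2.61) and with a pseudocount of 0.1 or 0.5 (3.32 and 2.93).

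Over all 11099 genes tested, limma called 5765 between B1 and B2, 2003 higher and 3762 lower in B1, and 1478 of them differed by at least 1 on the log2 scale (774 higher, 704 lower). The groups did not overlap for 61.7% of tested genes, where chance gives 10%. The median log2 fold change of all genes was −0.135. List medians and means are relative to the median of all genes only where the text says so. Median-of-ratios scaling moved that median to 0.002 and the calls to 2794 higher and 2520 lower, and quantile normalization gave 2477 and 2867. Spleen and peritoneal cavity, and the 2 strain labels, differ together with the cell type in this comparison and in the next, so none of these can be told apart there.

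**Figure D1:**
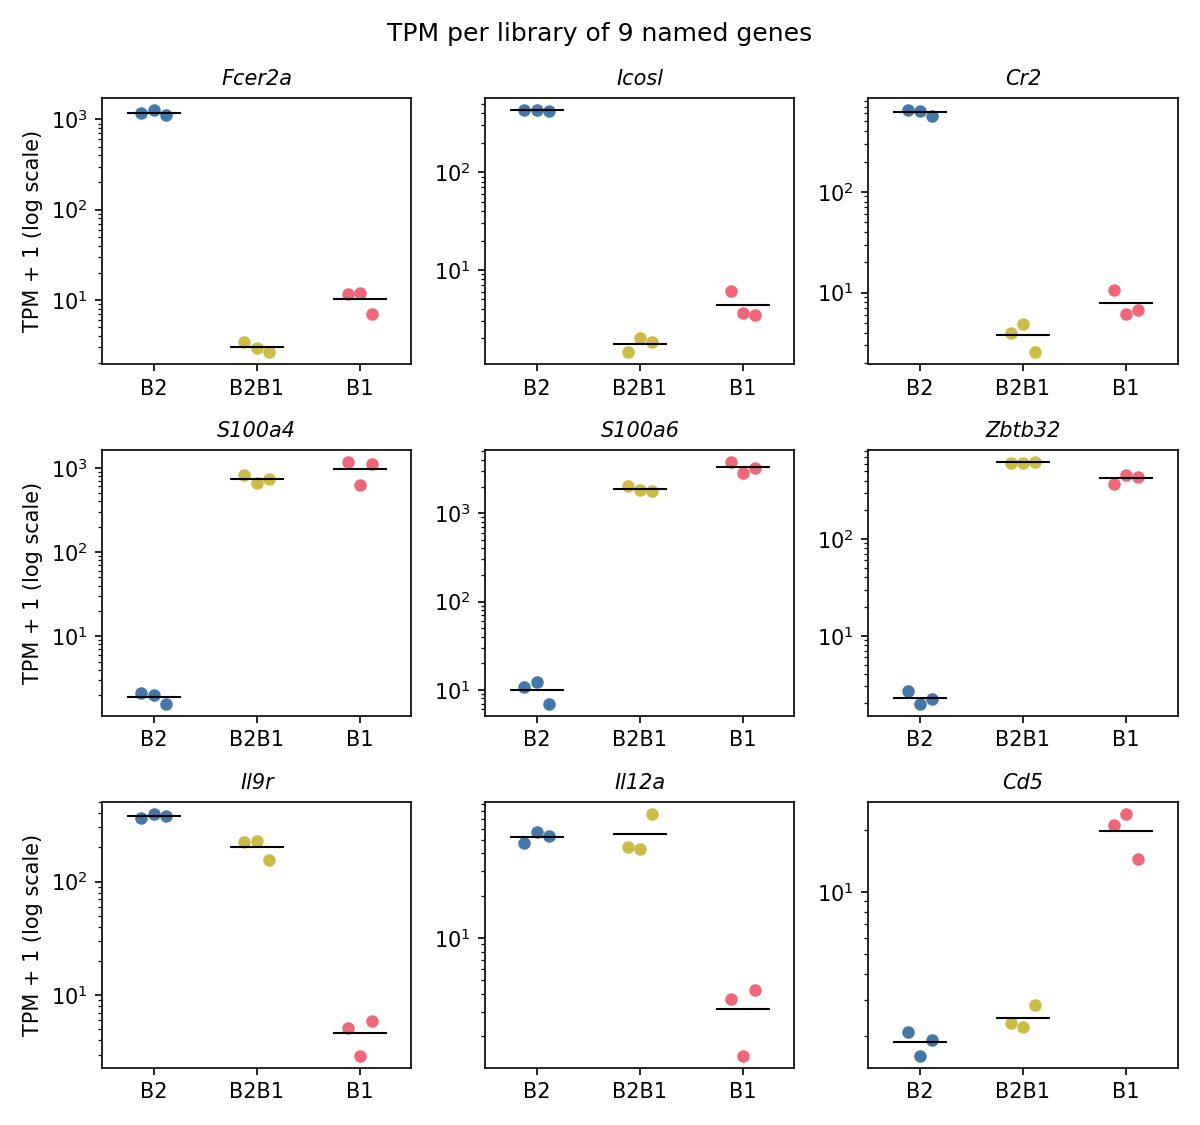
TPM + 1 per library (log axis) for 9 named genes in B2, B2B1 and B1 cells, each point 1 library and each bar the mean of 3. Fcer2a, Icosl and Cr2 stood at 427 to 1187 TPM on average in B2 and below 10 TPM in both peritoneal groups, while Il9r and Il12a averaged 3.63 and 2.13 TPM in B1 against at least 51.3 TPM in the other groups, and Cd5 was at 18.8 TPM in B1 against 0.874 TPM in B2 and 1.46 TPM in B2B1.

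The comparison of B2B1 with B2 cells addressed how the transcriptome of cells with a switched BCR differs from that of B2 cells. Zbtb32 was at 617 ± 9.08 TPM in B2B1 and 1.28 ± 0.347 TPM in B2 (log2 fold change 8.09 ± 0.115, limma adjusted p = 1.39e-09). S100a4 and S100a6 were higher in B2B1 by 8.60 ± 0.23 and 7.60 ± 0.20 on the log2 scale, reaching 734 ± 76.1 and 1895 ± 138 TPM. Fcer2a was at 1.99 ± 0.379 TPM (log2 fold change −8.64 ± 0.20, adjusted p = 6.56e-09). Icosl, the ligand of the T cell costimulator ICOS, was at 0.776 ± 0.281 TPM against 427 ± 5.38 TPM in B2 (−7.93 ± 0.20, adjusted p = 1.35e-08). Cr2 fell from 621 ± 45.6 TPM in B2 to 2.83 ± 1.16 TPM in B2B1 (log2 fold change −7.39 ± 0.25, adjusted p = 7.72e-08).

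The further genes with the highest fold changes were Fgl2, Tnfrsf8, Gas7, Anxa2, AI607873 and Gnb3, with log2 fold changes from 6.22 to 7.45, and Ctla4, which was listed at 0 in every B2 library and averaged 106 ± 54.0 TPM in B2B1. Tnfrsf8, the activation receptor CD30, was at 0.134 ± 0.110 TPM in B2 and 157 ± 27.7 TPM in B2B1. At the low end stood Vpreb3, Lmo2, Dennd3, Pde2a, Fam101b, Emid1 and Treml2, with log2 fold changes from −7.26 to −5.59. Lmo2, a transcriptional cofactor of blood cells, was at 335 ± 12.5 TPM in B2 and 2.90 ± 2.07 TPM in B2B1.

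B-1 cell markers were higher in B2B1 for 15 of 17 members and lower for 1 (the same adjusted over the list alone, median 4.65 relative to all genes, camera adjusted p = 1.66e-12, adjusted p = 0.00926 with an estimated correlation). Lgals1 was at 1023 ± 91.2 TPM and Cd9 at 363 ± 48.5 TPM in B2B1. Siglecg was the lower member, and its call was lost with median-of-ratios scaling (log2 fold change −0.04). Cd5, at 1.46 ± 0.338 TPM in B2B1 and 0.874 ± 0.243 TPM in B2, did not pass (log2 fold change 0.39 ± 0.20, adjusted p = 0.119), although it was called with median-of-ratios scaling (0.50). The submitters' signature, with the reservation given above, had 13 of 13 members higher and 12 of 12 lower, in the directions it has in B1 (the same adjusted over the lists alone, camera adjusted p = 1.66e-12 and 7.32e-08; adjusted p = 0.00501 and 0.0272 with an estimated correlation). Neurl3, a ubiquitin ligase gene in the lower part, was at 252 ± 11.8 TPM in B2 and 5.47 ± 0.862 TPM in B2B1.

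Follicular markers were lower for 8 of 11 members and higher for 1 (camera adjusted p = 0.00363, adjusted p = 0.297 with an estimated correlation). Marginal zone markers were lower for 7 of 10 and higher for 0 (camera adjusted p = 0.00358, adjusted p = 0.237 with an estimated correlation). S1pr3, Dtx1 and Marcks did not pass, although Marcks was called lower without B2B1 library 1 (log2 fold change −0.76) and with library weights (−0.60), and Marcks and S1pr3 with B2B1 library 1 and B1 library 2 both left out (−0.76 and −0.40). Dtx1, a Notch pathway gene, was at 175 ± 5.78 TPM in B2 and 162 ± 30.1 TPM in B2B1. Antigen presentation and costimulation genes were lower for 12 of 14 and higher for 2, Cd80 and Cd86 (camera adjusted p = 0.00609, adjusted p = 0.453 with an estimated correlation). H2-DMb1, a chain of class II peptide loading, was at 746 ± 59.9 TPM in B2 and 244 ± 17.2 TPM in B2B1 (log2 fold change −1.61 ± 0.07, adjusted p = 4.13e-07). In each of these 3 lists the counts adjusted over the list alone were the same.

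Higher in B2B1 than in B2 were also glycolysis genes, with 11 of 16 higher and 4 lower (camera adjusted p = 0.00115, adjusted p = 0.297 with an estimated correlation). Gapdh stood at 233 ± 4.11 TPM in B2 and 472 ± 9.45 TPM in B2B1, and Pfkp, a phosphofructokinase, at 18.7 ± 0.933 and 37.5 ± 1.39 TPM. The glucose transporter gene Slc2a3 was lower, at 9.13 ± 1.55 against 33.0 ± 4.20 TPM. Innate sensors had 10 of 14 higher and 3 lower (camera adjusted p = 0.00358; 0.297 as the adjusted p with an estimated correlation). Tlr2, one of them, was at 8.56 ± 0.158 and 30.0 ± 2.44 TPM. Plasma cell and secretory genes had 8 of 14 higher and 1 lower, the prolyl isomerase gene Fkbp11 (camera adjusted p = 0.00232; 0.297 as the adjusted p with an estimated correlation). Fkbp11 was at 15.6 ± 2.86 TPM in B2 and 2.04 ± 1.19 TPM in B2B1. Regulatory B cell genes had 7 of 12 higher and 2 lower (camera adjusted p = 0.00317, adjusted p = 0.121 with an estimated correlation). Lag3, an inhibitory receptor that binds class II molecules, was at 0.640 ± 0.274 TPM in B2 and 45.5 ± 25.5 TPM in B2B1 (log2 fold change 4.71 ± 0.34, adjusted p = 5.25e-06). Survival and apoptosis genes had 8 of 15 higher and 4 lower (camera adjusted p = 0.0196, adjusted p = 0.161 with an estimated correlation, and 0.073 by camera with median-of-ratios scaling). The antiapoptotic Mcl1 stood at 470 ± 25.9 TPM in B2 and 1080 ± 59.7 TPM in B2B1, and the proapoptotic Bbc3 at 2.95 ± 0.616 and 17.3 ± 1.03 TPM. The counts in these lists were the same adjusted over the list alone.

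Macrophage markers were higher in B2B1 for 7 of 7 tested members (7 adjusted over the list alone, camera adjusted p = 0.000754, adjusted p = 0.297 with an estimated correlation). Lyz2, which encodes lysozyme, was at 181 TPM in B2B1 library 1 and at 22.3 and 44.5 TPM in libraries 2 and 3, against 0.965 ± 0.546 TPM in B2. Emr1 was at 44.0 ± 6.91 TPM in B2B1. Cell cycle genes were higher for 9 of 21 and lower for 1 (the same adjusted over the list alone, camera adjusted p = 0.00363, adjusted p = 0.629 with an estimated correlation). Mki67 was at 28.2 TPM in B2B1 library 1, 12.2 and 10.3 TPM in libraries 2 and 3, and 1.67 ± 0.504 TPM in B2. The mean log2 value of this list was 4.29 in B2B1 library 1 and 3.52 and 3.49 in libraries 2 and 3.

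Further lists were not called in B2B1 against B2. BCR signalling components were lower for 12 of 18 and higher for 2 (camera adjusted p = 0.0806, and 0.0124 with quantile normalization). Immediate early genes were higher for 10 of 18 and lower for 5 (camera adjusted p = 0.0972), and were called as a list without B2B1 library 1 (0.0446), also with B1 library 2 left out as well (0.0329). Atf3, a stress-response transcription factor, was at 0.444 ± 0.183 TPM in B2 and 34.2 ± 16.1 TPM in B2B1, and the phosphatase gene Dusp2 at 149 ± 11.2 and 6.70 ± 2.96 TPM. Interferon-stimulated genes were higher for 3 of 18 and lower for 1 (2 and 0 adjusted over the list alone, camera adjusted p = 0.343), with a mean log2 value of 3.46 and 3.67 in B2B1 libraries 2 and 3 and 5.36 in library 1. Inhibitory receptors and phosphatases had 3 members higher and 9 lower of 15 (camera adjusted p = 0.569), homing and adhesion receptors 4 and 7 of 17 (0.638), B cell transcription factors 7 and 12 of 23 (0.92), germinal centre genes 3 and 2 of 6 (0.343), lipid uptake and metabolism genes 2 and 11 of 20 (0.343), dendritic cell markers 2 and 2 of 5 (0.802) and T cell markers 0 and 1 of 4 (0.92). These counts were the same adjusted over the list alone. The camera direction was up for homing receptors, transcription factors and dendritic cell markers, whose medians (−0.15, −0.29 and −0.06, or 0.047, −0.101 and 0.135 relative to all genes) and means (−0.07, −0.09 and −0.11) were negative. For interferon-stimulated genes it was up with a median of 0.01 and a mean of −0.12, and for inhibitory receptors it was down with a mean of 0.15.

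In total 6995 of 11099 genes were called between B2B1 and B2, 2332 higher and 4663 lower, with 1917 at an absolute log2 fold change of at least 1 (906 higher, 1011 lower). The groups did not overlap for 72.2% of tested genes, against 10% by chance. Around a median log2 fold change of −0.193 for all genes, median-of-ratios scaling gave 3374 higher and 3179 lower calls and quantile normalization 2973 and 3538.

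Both peritoneal groups shared most of their differences from B2. Limma called 1635 genes higher in both B1 and B2B1 than in B2, where independent lists would share 421, and 3364 lower in both, where independent lists would share 1581. Another 55 genes were called in opposite directions. Across the tested genes, which are not independent replicates, the log2 fold changes correlated with Pearson's r = 0.881 and Spearman's rho = 0.853. Simulated libraries with no effect, with a simulated B2 group shared by both comparisons, gave 0.502 and 0.46. The covariance of the log2 fold changes was 0.821 against 0.0187 in the simulations, a difference of 0.802. Genes called in both comparisons numbered 5054, against 0.01 on average in the simulations. The simulations hold no real differences, so they do not show how much shared controls add where genes differ. The numbers for independent lists leave out the shared controls, and the 3 B2 libraries are too few to split. Part of the excess of shared calls over the numbers for independent lists may therefore come from these controls.

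For each of the 1478 genes that differed by at least 1 on the log2 scale between B1 and B2, the level in B2B1 was placed on a scale with B2 at 0 and B1 at 1. The median position was 1.01 (quartiles 0.77 and 1.23), and the 3 B2B1 libraries gave 1.03, 1 and 1.01 (mean 1.01, SD 0.0185). That SD covers the B2B1 libraries alone, because the B2 and B1 means were held fixed. Of these genes, 1313 (88.8%) lay closer to B1 and 165 closer to B2. The level in B2B1 lay past that in B1 for 767 genes and below 0 for 26. The 774 genes higher in B1 had a median position of 0.985 and the 704 lower ones of 1.03.

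**Figure D2:**
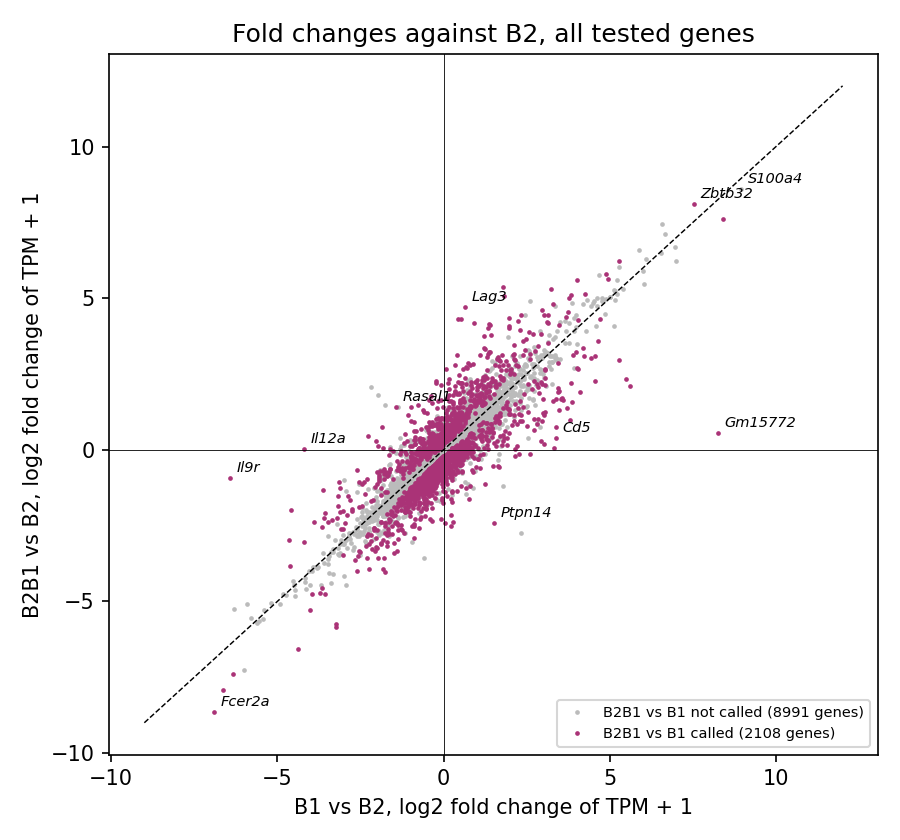
Log2 fold changes of TPM + 1 against B2 for the 11099 tested genes, B1 on the x axis and B2B1 on the y axis, with the dashed line at equal values and the 2108 genes called between B2B1 and B1 in purple. Il9r and Il12a lie at −6.42 and −4.20 on the x axis and at −0.93 and 0.02 on the y axis, Cd5 at 3.38 and 0.39, Lag3 at 0.65 and 4.71, and Gm15772, labelled after its values were seen, at 8.26 and 0.55.

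The comparison of B2B1 with B1 cells, which shared tissue and strain label, addressed what still differed between cells with a switched BCR and B1 cells. It was not balanced for Xist and Y-linked transcripts. All B1 libraries had Xist above 10 TPM, while B2B1 libraries 1 and 2 had Xist at 0.461 and 0.355 TPM and Ddx3y at 56.9 and 61.7 TPM. A difference that follows these transcripts cannot be fully told apart from one between the groups. Il9r stood at 202 ± 42.1 TPM in B2B1 and 3.63 ± 1.53 TPM in B1 (log2 fold change 5.49 ± 0.25, limma adjusted p = 7.52e-06). Il12a was at 53.9 ± 18.9 TPM in B2B1, 51.3 ± 4.75 TPM in B2 and 2.13 ± 1.48 TPM in B1 (log2 fold change 4.22 ± 0.38, adjusted p = 0.000234). Cd5 was lower in B2B1 than in B1, at 1.46 ± 0.338 against 18.8 ± 4.88 TPM (log2 fold change −2.98 ± 0.20, adjusted p = 8.46e-05). Lag3 was at 45.5 ± 25.5 TPM in B2B1, 1.62 ± 0.666 TPM in B1 and 0.640 ± 0.274 TPM in B2 (log2 fold change against B1 4.06 ± 0.34, adjusted p = 0.000187). Ptpn14, a cytoplasmic tyrosine phosphatase, was at 0.951 ± 0.362 TPM in B2B1 and 31.8 ± 15.04 TPM in B1 (log2 fold change −3.95 ± 0.34, adjusted p = 0.000197).

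By position in GRCm38 (GENCODE M21), Il9r lies on chromosome 11 from 32187541 to 32200279, Il12a on chromosome 3 from 68690644 to 68698547, Cd5 on chromosome 19 from 10717116 to 10739002 and Ptpn14 on chromosome 1 from 189728268 to 189876695. The remaining genes with the highest fold changes in B2B1 were Gstt1, Ndrg1, Slc9a3r2, Gbp10, Sytl1, Rasal1 and Serpinb8, with log2 fold changes from 2.79 to 3.90. Gstt1 and Slc9a3r2 were listed at 0 in all B2 libraries. Sytl1, of vesicle docking, was at 81.4 ± 18.4 TPM in B2B1 and 7.58 ± 1.14 TPM in B1 (3.25 ± 0.16, adjusted p = 9.42e-06). Krt8, Fbxw13, Fzd6, AI427809, Fkbp11, Pygl, Dennd3 and Pde2a stood at the low end together with Ptpn14 and Cd5, with log2 fold changes from −3.49 to −2.51. Krt8, a keratin, was at 3.76 ± 2.27 TPM in B2B1 and 48.6 ± 5.31 TPM in B1, and Fzd6, a Wnt receptor, at 1.95 ± 0.208 and 20.3 ± 3.62 TPM. The call of Pde2a (adjusted p = 0.0164) was lost when only the 6 libraries of both groups were fitted and with a covariate for Xist above 10 TPM, at log2 fold changes of −2.51 and −2.49 against −2.51.

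B-1 cell markers were divided between B2B1 and B1, with 5 of 17 higher and 4 lower (6 and 4 adjusted over the list alone, camera adjusted p = 0.126). Cd9 and Lgals1 were higher in B2B1 (log2 fold changes 1.31 ± 0.09 and 0.93 ± 0.10, adjusted p = 8.62e-05 and 0.000636). The interleukin 5 receptor gene Il5ra was lower, at 60.5 ± 11.6 TPM in B2B1 and 177 ± 37.2 TPM in B1 (−1.53 ± 0.18, adjusted p = 0.000907). The submitters' signature had 3 of 13 members higher and 1 lower in its part that is higher in B1 (3 and 2 adjusted over the list alone, camera adjusted p = 0.296), and 0 of 12 higher and 5 lower in the other part (1 and 5, camera adjusted p = 0.119). That second part was called as lower without B1 library 1 (camera adjusted p = 0.0464) and with median-of-ratios scaling (0.0454). Follicular markers were lower in B2B1 for 4 of 11 and higher for 0 (5 and 0 adjusted over the list alone, camera adjusted p = 0.184, and 0.0381 without B2B1 library 2). Cd55 was at 60.9 ± 6.90 TPM in B2B1 and 139 ± 17.0 TPM in B1.

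Interferon-stimulated genes were higher in B2B1 than in B1 for 7 of 18 members and lower for 0 (8 and 0 adjusted over the list alone, median 1.21 relative to all genes, camera adjusted p = 2.21e-06, adjusted p = 0.462 with an estimated correlation). Without B2B1 library 1 the list stayed called (camera adjusted p = 5.84e-06), but its median log2 fold change, not taken relative to all genes, went from 1.15 to 0.63. The spread among B2B1 libraries was wide in this list: Irf7 stood at 56.1, 12.9 and 25.6 TPM in B2B1 libraries 1 to 3 and at 6.74 ± 0.0602 TPM in B1. The call of Irf7 was lost with only the 6 libraries of both groups and with a covariate for Xist above 10 TPM, where its log2 fold changes were 1.84 and 1.88, against 1.84 with all libraries and no covariate. Macrophage markers were higher for 3 of 7 and lower for 0 (7 and 0 adjusted over the list alone, camera adjusted p = 0.000542, adjusted p = 0.462 with an estimated correlation). Emr1 was at 44.0 ± 6.91 TPM in B2B1 and 18.1 ± 3.90 TPM in B1 (log2 fold change 1.25 ± 0.17, adjusted p = 0.00158), while Lyz2 ranged from 22.3 to 181 TPM in B2B1 and from 1.22 to 30.9 TPM in B1 and did not pass. The calls of the other members, Alox15 and C1qa, had log2 fold changes of 1.99 and 1.47. Both calls were lost without B2B1 library 1 (1.41 and 1.09), B2B1 library 3 (1.98 and 1.44), B1 library 1 (1.61 and 1.07) or any B2 library (1.99 and 1.47). That of Alox15 was also lost without B1 library 3 (2.06), and that of C1qa without B1 library 2 (1.59). Both were also lost with only the 6 libraries of both groups (1.99 and 1.47) and with a covariate for Xist above 10 TPM (2 and 1.53), among other alternatives.

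Glycolysis genes were higher in B2B1 for 8 of 16 and lower for 1, the glucose transporter gene Slc2a1 (10 and 3 adjusted over the list alone, camera adjusted p = 0.00142, adjusted p = 0.462 with an estimated correlation). Pfkp was at 37.5 ± 1.39 TPM in B2B1 and 24.6 ± 1.16 TPM in B1, and Slc2a1 at 37.8 ± 7.18 and 70.6 ± 5.18 TPM. Cell cycle genes were called as a list (camera adjusted p = 0.00865, adjusted p = 0.548 with an estimated correlation), although limma called 0 of the 21 members, over all genes or adjusted over the list alone, and 0 reached an unadjusted p under 0.05. That list call was lost without B2B1 library 1 (camera adjusted p = 0.157), without B1 library 1 (0.116), without B1 library 3 (0.0556) and with a covariate for Xist above 10 TPM (0.069). Mki67 was at 19.5 TPM in B1 library 2 and at 2.98 and 3.19 TPM in B1 libraries 1 and 3. Without B1 library 2 the list stayed called (camera adjusted p = 9.93e-08), and its median log2 fold change, not taken relative to all genes, went from 0.387 to 0.819. Mki67, Top2a, Ccnb1 and Cdk1 were then called higher in B2B1 (log2 fold changes 2, 1.74, 1.07 and 1.15).

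Survival and apoptosis genes were higher for 4 of 15 and lower for 1 (6 and 1 adjusted over the list alone, camera adjusted p = 0.0264, adjusted p = 0.462 with an estimated correlation; 0.065 without B2B1 library 1). The higher members that passed, Bbc3, Pmaip1, Bax and Fas, encode proapoptotic proteins, with Bbc3 at 17.3 ± 1.03 TPM in B2B1 and 6.18 ± 1.93 TPM in B1. The call of Fas was lost without B1 library 1 or 3 or B2B1 library 1 or 3 (log2 fold changes 0.93, 1.05, 1.02 and 0.97, against 1.10 with all), and also with only the 6 libraries of both groups (1.10). With a covariate for Xist above 10 TPM the calls of Fas and Pmaip1 were lost (1.11 and 1.44, against 1.10 and 1.43 without it). Immediate early genes were higher for 4 of 18 and lower for 1 (8 and 2 adjusted over the list alone, camera adjusted p = 0.025, adjusted p = 0.508 with an estimated correlation). Egr3, a transcription factor induced by antigen receptor signals, was at 30.9 ± 4.32 TPM in B2B1 and 8.85 ± 2.44 TPM in B1, and Nr4a1, an orphan nuclear receptor induced by the same signals, at 31.7 ± 3.08 and 12.7 ± 3.13 TPM. Their list call was lost without B2B1 library 3 (camera adjusted p = 0.151), without B1 library 1 (0.0736), and with median-of-ratios scaling (0.081) or quantile normalization (0.0695). Regulatory B cell genes were higher for 4 of 12 and lower for 2 (5 and 2 adjusted over the list alone, camera adjusted p = 0.036, adjusted p = 0.462 with an estimated correlation), and that call too was lost in several alternatives. It was lost without B2B1 library 1 (camera adjusted p = 0.0853), without B1 library 2 (0.0758) and without both (0.14), with median-of-ratios scaling (0.081) or quantile normalization (0.0695), and with a covariate for Xist above 10 TPM (0.0751).

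**Figure D3:**
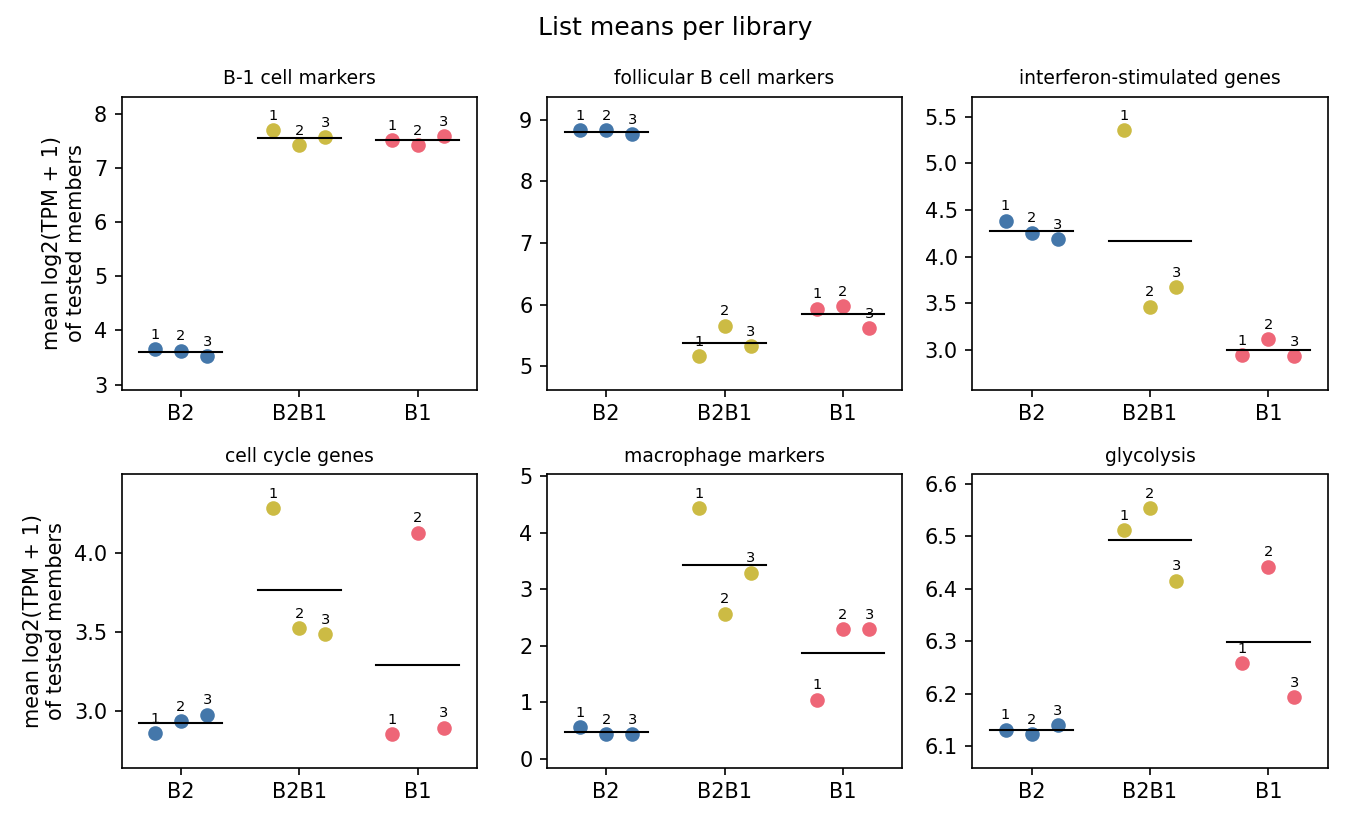
Mean log2(TPM + 1) over the tested members of 6 gene lists, each point 1 library with its number and each bar the mean of 3 libraries. B-1 and follicular markers parted B2 from both peritoneal groups, B2B1 library 1 was highest for interferon-stimulated genes (5.36), macrophage markers (4.43) and cell cycle genes (4.29), and B1 library 2 reached 4.13 for cell cycle genes.

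Other lists were not called between B2B1 and B1. Plasma cell and secretory genes had 5 of 14 higher and 1 lower (6 and 2 adjusted over the list alone, camera adjusted p = 0.0548), and their list was called without B1 library 2 (0.0286), without B2B1 library 2 (0.0327), without B2 library 1 or 3 (0.0473 and 0.0483), with B2B1 library 1 and B1 library 2 both left out (0.0401) and with a covariate for Xist above 10 TPM (0.0307). Fkbp11 was at 2.04 ± 1.19 TPM in B2B1 and 18.2 ± 3.40 TPM in B1. BCR signalling components had 3 higher and 7 lower of 18 (the same adjusted over the list alone, camera adjusted p = 0.184), with Rasgrp3 higher (19.6 ± 5.63 against 5.31 ± 1.60 TPM). Lipid uptake and metabolism genes had 3 higher and 2 lower of 20 (3 and 3 adjusted over the list alone, camera adjusted p = 0.515). The cholesterol exporter gene Abca1 was at 9.65 ± 3.08 TPM in B2B1, 58.6 ± 24.5 TPM in B1 and 53.8 ± 5.13 TPM in B2 (log2 fold change against B1 −2.45 ± 0.28, adjusted p = 0.000726). Inhibitory receptors and phosphatases had 1 higher and 5 lower of 15 (the same adjusted over the list alone; 0.31), homing and adhesion receptors 2 and 2 of 17 (5 and 5; 0.905), B cell transcription factors 6 and 4 of 23 (7 and 5; 0.184), marginal zone markers 2 and 2 of 10 (4 and 2; 0.551), germinal centre genes 1 and 0 of 6 (1 and 0; 0.169), innate sensors 2 and 2 of 14 (2 and 2; 0.184) and antigen presentation and costimulation genes 0 and 2 of 14 (1 and 3; 0.536). Among the higher members, the calls of S1pr3 (marginal zone) and Tlr9 (innate sensors) were lost without B2 library 1, 2 or 3, B2B1 library 1 or 2, or B1 library 1 or 2. That of Itgb1 (homing) was lost without B2 library 1, B2B1 library 1, 2 or 3, or B1 library 1 or 3. For the homing receptors, marginal zone markers, transcription factors, lipid genes and the signature part higher in B1, the camera direction was up while a median (−0.06 and −0.01 for the first 2, or 0 and 0.052 relative to all genes) or a mean (−0.02, −0.01 and −0.01 for the others) was negative.

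T cell markers had 0 higher and 2 lower of 4 tested in B2B1 against B1 (the same adjusted over the list alone, camera adjusted p = 0.2). The call of Cd3d, among the lower members, was lost without B2 library 1 or 2, B2B1 library 1 or 2, or B1 library 1, 2 or 3. It was also lost with quantile normalization and with a covariate for Xist above 10 TPM. Cd3g was at 0.372 ± 0.128 TPM in B2B1 and 7.81 ± 2.51 TPM in B1 (log2 fold change −2.65 ± 0.20, adjusted p = 0.000154). Of these markers, 7 of the 12 listed stayed under 1 TPM in every library. Dendritic cell markers had 1 higher and 0 lower of 5 (the same adjusted over the list alone, camera adjusted p = 0.376). Prf1, the one tested NK cell marker, was at 13.7 ± 2.51 TPM in B2, 0.537 ± 0.213 TPM in B2B1 and 0.971 ± 0.268 TPM in B1, lower in both peritoneal groups than in B2 (adjusted p = 1.03e-06 and 2.55e-06). Cxcr2 and Csf3r were the tested neutrophil markers, and Cxcr2 averaged 18.7 ± 0.767 TPM in B2, 8.32 ± 0.792 TPM in B2B1 and 11.9 ± 1.78 TPM in B1, while Csf3r averaged 2.98 ± 0.236, 3.31 ± 0.737 and 4.03 ± 0.302 TPM. Cxcr2 was lower in both peritoneal groups than in B2, and Csf3r did not pass in B1 against B2 (adjusted p = 0.069), although its call appeared without B2B1 library 3 (log2 fold change 0.34), in the 6-library fit (0.34) and with median-of-ratios scaling (0.45). Hba-a1 and Hba-a2 were the tested erythroid markers, with no call in any comparison by limma, 0 also at an unadjusted p under 0.05, and at most 5.47 TPM in a library. With B2B1 library 1 and B1 library 2 both left out, Hba-a2 was called lower in B2B1 than in B2 (log2 fold change −1.19). Mast cell and eosinophil markers reached at most 2.06 TPM and mesothelium and stroma markers at most 0.667 TPM. Igj, the joining chain gene, was at 4.62 ± 2.79, 3.92 ± 0.820 and 2.32 ± 0.789 TPM in B2, B2B1 and B1, with no call, although it was called lower in B1 than in B2 without B2 library 3 (log2 fold change −1.02).

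Between B2B1 and B1, 2108 of 11099 genes were called, 769 higher and 1339 lower in B2B1, and 413 of them differed by at least 1 on the log2 scale (209 higher, 204 lower). The groups did not overlap for 35.7% of tested genes, where chance gives 10%. Around a median log2 fold change of −0.056, median-of-ratios scaling gave 1021 higher and 961 lower calls, and quantile normalization 912 and 983. The count fell to 1341 without B1 library 1, to 1129 with only these 6 libraries in the fit and to 842 with a covariate for Xist above 10 TPM. Gm15772, a processed pseudogene named here after its values were seen, stood at 2267 ± 93.3 TPM in B1 and 9.89 ± 1.51 TPM in B2B1, and the ribosomal protein gene Rpl26 at 1955 ± 74.2 and 4318 ± 134 TPM. Their sequences are identical at 436 of 438 aligned bases, so the split of reads between these 2 genes is uncertain.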

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

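The comparison of directions below and all tests of chance were chosen after the results were seen. Among genes with a mean of at least 5 TPM, 3 differed from B2 in opposite directions in B1 and B2B1, by at least 1 on the log2 scale each way. This choice forces a log2 difference of at least 2 between B2B1 and B1, so a test of that difference would be no separate evidence and none is given here. Ptpn14, the tyrosine phosphatase, was at 9.37 ± 0.425 TPM in B2, 0.951 ± 0.362 TPM in B2B1 and 31.8 ± 15.04 TPM in B1 (mean ± SD, n = 3). Its log2 fold change between B2B1 and B1 was −3.95 ± 0.34 (SE). Rasal1, which encodes a Ras GTPase-activating protein, was at 19.7 ± 3.73, 53.0 ± 5.90 and 6.67 ± 0.501 TPM in B2, B2B1 and B1, a log2 difference between the peritoneal groups of 2.81 ± 0.14. Lilrb4, an inhibitory receptor gene, was at 23.2 ± 5.40, 52.8 ± 8.97 and 11.2 ± 5.34 TPM, a log2 difference of 2.23 ± 0.31. Its call as lower in B1 than in B2 (log2 fold change −1.07, limma adjusted p = 0.0182) was lost without B2 library 1 (−0.89). Why they differ was not tested.

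Each comparison sets 3 libraries against 3, and 10 splits of 6 libraries are too few for a share under 0.05. In the fit of all 9 libraries, the real split called 5765 genes between B1 and B2, and the highest of the other splits 1. Between B2B1 and B2 the counts were 6995 and 5, and between B2B1 and B1 2108 and 1. In each comparison 1 of the 10 splits, the real one, called as many genes as the real one. Every other split mixes libraries of both groups, so a real difference enters the spread and lowers its calls. The low counts of the other splits therefore do not measure what chance alone would call.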

How the results depend on the processing

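The alternatives with a covariate for Xist, with B2B1 library 1 and B1 library 2 both left out, and with other scalings for the gene lists were chosen after the data were seen. No list or named gene changed direction under an alternative while called in either fit, but uncalled ones did, such as Dtx1 and Igj in B2B1 vs B2 (log2 fold changes −0.13 and −0.08, and 0.08 for both with median-of-ratios scaling). The balance of calls turned too. Median-of-ratios scaling gave more higher than lower calls in B1 vs B2 (2794 and 2520, against 2003 and 3762), B2B1 vs B2 (3374 and 3179, against 2332 and 4663) and B2B1 vs B1 (1021 and 961, against 769 and 1339). So did the fold threshold below in B1 vs B2 (774 and 704) and B2B1 vs B1 (209 and 204). Requiring a log2 fold change of at least 1 reduced the 5765, 6995 and 2108 genes called in B1 vs B2, B2B1 vs B2 and B2B1 vs B1 to 1478, 1917 and 413, by construction. The last count was 1129 with only the 6 libraries compared, while the same setting gave 5640 in B1 vs B2 and 7298 in B2B1 vs B2. It was 842 in B2B1 vs B1 with the Xist covariate. The cause of neither fall was tested. Leaving out 1 library gave 4759 to 5942, 6104 to 7358, and 1341 (without B1 library 1) to 2445 (without B1 library 2). Of the 23 lists, 11, 13 and 7 were called, and 3, 3 and 0 with an estimated correlation, where camera gave 5, 5 and 1 at an unadjusted p under 0.05. In both comparisons with B2, the 3 were the B-1 cell markers and both parts of the submitters' signature. Those parts were split by the B1 and B2 means of these same libraries, so they are not independent evidence. Leaving out 1 library gave 11 to 12, 13 to 14, and 4 (without B2B1 library 1) to 9 (without B2B1 library 2) lists. The median position of 1.01 moved to 1.03 with a mean of at least 5 TPM, 1.12 over all genes called and 0.957 without both libraries, and ranged from 0.974 (without B1 library 2) to 1.02 (without B2B1 library 2) with 1 library out. The cause of these shifts was not tested. Same-numbered libraries correlated at −0.058 to 0.123 in their deviations from the group means, and not every library correlated best with its own number. With 3 libraries per group these correlations are too few to show or exclude a pairing by number. With the replicate number as a block, 5533, 6855 and 1737 genes and 11, 13 and 7 lists were called. The 20 top genes of each comparison kept their calls in all 460 results for B1 vs B2 and for B2B1 vs B2, and in 458 for B2B1 vs B1, where 2 results for Pde2a were lost. For the other named genes, calls were lost in 30, 22 and 191 results and gained in 20, 30 and 22. The losses include calls that the fold threshold removed by construction. Removal of immunoglobulin or mitochondrially encoded genes was not run, and the immunoglobulin share was not analysed here. TPM keep no depth, so a limit set by counting error could not be given.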

Other observations

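The genes and tests in this part were chosen after their values were seen. H2-Q4, a nonclassical class I gene, was at 767 ± 52.2 TPM in B2, 870 ± 31.6 TPM in B2B1 and 420 ± 29.7 TPM in B1 (B2B1 vs B1 log2 fold change 1.05 ± 0.07, limma adjusted p = 8.46e-05). H2-Q6 was at 463 ± 14.8, 577 ± 59.5 and 259 ± 46.1 TPM (1.16 ± 0.12, adjusted p = 0.000521). Class I genes are near-identical, so the division of reads among them is uncertain. Tap1, a peptide transporter, was at 236 ± 3.11, 221 ± 13.97 and 127 ± 15.7 TPM (0.80 ± 0.09, adjusted p = 0.000586). These are single genes and no list: the antigen presentation list fixed beforehand had 0 higher and 2 lower of 14 in B2B1 vs B1 (1 and 3 adjusted over the list alone, camera adjusted p = 0.536). Itga6, the integrin alpha 6 chain, was at 5.10 ± 0.625 TPM in B2, 6.48 ± 1.01 TPM in B2B1 and 17.6 ± 1.27 TPM in B1 (B2B1 vs B1 −1.32 ± 0.125, adjusted p = 0.000285). P2rx7, an ATP-gated channel, was at 3.00 ± 0.251, 4.57 ± 1.498 and 12.3 ± 2.91 TPM (−1.27 ± 0.22, adjusted p = 0.00531). Of the 1635 genes higher in both peritoneal groups than in B2, limma called B2B1 above B1 in 272 and below it in 130. Of the 3364 lower in both, limma called B2B1 below B1 in 601 and above it in 100. These counts come from TPM without rescaling and were not recomputed with other scalings. Median-of-ratios scaling turned the balance of calls in B2B1 vs B1, from 769 higher and 1339 lower to 1021 and 961.

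Some genes stood in B2B1 at 50% or more of their B2 level and were low in B1, 25 in all. Marcksl1, for example, was at 49.5 ± 3.46 TPM in B2, 84.3 ± 12.8 TPM in B2B1 and 12.9 ± 0.666 TPM in B1, but the 25 also include Rpl26, whose reads cannot be divided safely from those of Gm15772, and Oas1a and Oas2, which spread widely in B2B1 (26.1 ± 22.2 and 33.9 ± 29.2 TPM). B2 cells among the B2B1 samples would need a share of 37.3% at the lowest and 105% at the median. In contrast, 7 transcripts outside the 25 that were abundant in B2 and nearly absent from B1, such as Fcer2a, stood far lower. They were at 0.168 to 2.95% of their B2 level (median 0.456%), which argues against B2 cells as the source. Il9r also met these limits but, as a member of the 25, was left out. It was at 379 TPM in B2, 202 TPM in B2B1 and 3.63 TPM in B1. With a covariate for Xist above 10 TPM, 21 of the 25 stayed called and the median log2 fold change went from 1.45 to 1.62, which argues against the mix of Xist-high and Xist-low libraries as the whole cause. A difference in the history of the cells may remain, and was not tested.

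Of 7 macrophage markers, 3 were called higher in B2B1 than in B1, and the list was called with a preset correlation (camera adjusted p = 0.000542) but not with an estimated one (adjusted p = 0.462). Over the 5 markers other than Emr1 and Lyz2, B2B1 library 1, singled out by its Lyz2, stood above the mean of the other B2B1 libraries by a median ratio of 3.29, while the median ratio of all tested genes was 1.02, consistent with RNA of peritoneal macrophages in that library. That ratio does not address B2B1 against B1, where Alox15 and C1qa were the 2 of these 5 called and both calls were lost without any 1 of several libraries, B2B1 library 1 among them (log2 fold changes 1.41 and 1.09), so this source and a biological difference cannot be told apart. The ratio of Emr1 to Lyz2 varied 56.3-fold among the 6 peritoneal libraries and 6.21-fold without B1 library 1. For C1qa, C1qb and C1qc it varied at most 5.34-fold and 2.54-fold. B1 library 1 had Emr1 at 19.7 TPM with Lyz2 at 1.22 TPM. In B2B1 library 1, Emr1 was only 1.3 times the mean of the other B2B1 libraries. Each of these values rests on a single library. Over all 6, however, Emr1 stayed at 39.9 to 52.0 TPM in B2B1 and 13.6 to 20.9 TPM in B1. Lyz2 ranged from 22.3 to 181 TPM and from 1.22 to 30.9 TPM in the same libraries. Emr1 thus did not follow Lyz2 within either group, which argues against macrophage RNA as the main source of Emr1 in these libraries. A smaller part from macrophages stays open, and other sources of Emr1 were not tested. A sort or gate that would remove macrophages is not given in the sources used here.

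Gm15772, a processed pseudogene on chromosome 5 from 3236431 to 3236868 (GRCm38), stood at 2187 to 2369 TPM in the B1 libraries and 5.73 to 11.2 TPM in the others, while Rpl26 stood at 1877 to 2025 and 3836 to 4470 TPM. Their sums were 3947 ± 108 TPM in B2, 4328 ± 134 TPM in B2B1 and 4222 ± 166 TPM in B1, a log2 difference of 0.1 between B1 and B2, consistent with reads of Rpl26 counted for the pseudogene in B1. Of 89 other pseudogenes, processed and unprocessed together, limma called 11 between B2B1 and B1. Of these, 0 were higher in B1 by log2 2 or more (0 also at an unadjusted p under 0.05). That argues against a processing difference for all pseudogenes. How many of the 89 were processed was not counted, so a difference for processed pseudogenes alone cannot be judged. B1 and B2B1 share a strain label, yet the lowest B1 value of Gm15772 was 196 times the highest B2B1 value, which argues against a variant that follows that label. A variant of the B1 mice alone stays open, as does a biological difference, and neither was tested.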
